A study of Mus musculus with 6 samples.

How the data were processed

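RNA was measured in intestine from newborn C57BL/6 mice, an inbred laboratory strain, after 5 days with NECA or with DMSO, in 3 libraries per group. NECA (N-ethylcarboxamidoadenosine) is an adenosine analogue that activates adenosine receptors of more than 1 subtype, and DMSO is the solvent used as the vehicle control. Per the labels' protocols, complementary DNA was made with SMARTer chemistry, amplified by PCR, fragmented and sequenced in paired ends on a NovaSeq instrument. Amplified reads without molecular identifiers are not independent molecules, so counting error understates the error of low genes. The labels give neither the segment of bowel nor the way NECA was given, and they do not say whether the 3 libraries of a group came from separate animals. The p-values therefore measure the spread between these libraries, part of which may be technical.

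For each library the authors deposited a whole-number count per gene, not normalized, for 54532 genes, with the gene identifier and name. Beside each count the authors deposited an FPKM value (fragments scaled by transcript length and library size), per the file headers. The FPKM values were the counts divided by 1 value per gene and 1 factor per library, with a largest relative deviation of 4e-07. The library factors differed from the library totals: relative to DMSO replicate 1, the factor of NECA replicate 2 was 1.121 and its total was 1.008. Only the counts were tested. Per the submitters' processing notes, which name HISAT, StringTie and edgeR and the mouse builds mm10 and GRCm38, reads were processed with these tools. Versions, parameters, strand setting and the treatment of reads matching several places are not given in the sources used here. Values of near-identical genes such as the Defa alpha-defensins, Reg3b and Reg3g, the Ifit genes, the Serpina1 genes and ribosomal protein genes are therefore uncertain, as are those of overlapping genes on opposite strands such as mt-Nd6. Coordinates are from GENCODE mouse release M21 on GRCm38, in which 54409 of the identifiers (99.77%) were found.

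Total counts ran from 15531996 in DMSO replicate 2 to 18065078 in NECA replicate 2, and 21564 to 21946 genes had at least 1 count. Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 15847 genes. They were scaled with TMM factors and tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest), NECA against DMSO, without covariates, in R 4.3.3. P-values were two-sided and Benjamini-Hochberg adjusted, with a threshold of 0.05. Levels are given as TMM-normalised CPM (counts scaled to library size), mean ± SD over the 3 libraries of a group. Fold changes are log2 of NECA over DMSO, with a standard error (SE) taken from the fold change and its F statistic. The common biological coefficient of variation was 0.276, and 0.213 without NECA replicate 2.

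A set of 52 gene lists (cell types, bowel regions and pathways) was written from general knowledge of newborn intestine, adenosine signalling and myeloid cells. Camera (limma 3.58.1) tested the 50 lists with at least 5 tested genes against the other genes, with a preset correlation between genes of 0.01 and adjustment over lists. The gastric list had 2 tested genes and the Y-linked list had 0, so neither was tested. Camera was repeated with a correlation estimated from the residuals, and fry was run as a test of each list alone. Members of a list were also adjusted over the list alone.

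Named genes followed a rule: in each direction, up to 10 genes past the adjusted threshold with groups that did not overlap and a mean of at least 10 CPM in the higher group, or, failing that, the 5 with the smallest p that met the same limits on overlap and level. Predicted genes without a name were left out. Up to 4 leading members of each list past its threshold and a set of adenosine receptor, myeloid and epithelial genes were named as well. Some genes that the rule would name are not reported here. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined. The alternatives were another scaling (DESeq2 size factors), no filter or a stricter filter (5 CPM), a replicate block, each library left out in turn, library quality weights, DESeq2 1.42.0, a fold threshold (log2 of 1), other list tests, and leaving mitochondrial, haemoglobin and ribosomal protein genes out. Added after seeing the data were a fit without both replicates numbered 2, sex and bowel position as covariates, robust dispersions, DESeq2 without NECA replicate 2, and the estimated correlation with each library left out in turn. The position score was the mean of the jejunum list minus that of the ileum list.

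The scripts were tested on counts simulated from the means of the 15847 genes with 3 libraries per group. For NECA against DMSO with all 6 libraries, 13% of genes given a 2-fold change and 81% of those given a 4-fold change were recovered, with 9 false calls, and 0 of 30 unchanged lists had a p under 0.05. For the 5 libraries without NECA replicate 2 (16121 genes), 35% and 78% were recovered, with 17 false calls, and 2 of 30 unchanged lists had a p under 0.05. The simulated genes varied independently, unlike genes in tissue that holds several cell types. In each run 100 genes were given each fold change, and no library was set apart from the rest. The recovered shares therefore need not hold for the deposited libraries. There Gatm, at a log2 fold change of -2.26, had an edgeR adjusted p of 0.738.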

Results

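Transcript counts were obtained from the intestine of newborn mice after 5 days with the adenosine receptor agonist NECA or with the vehicle DMSO, in 3 libraries per group. The series title places the comparison in work on adenosine, necrotizing enterocolitis (an inflammatory disease of the newborn bowel) and myeloid-derived suppressor cells (MDSCs). The DMSO libraries held 17922697, 15531996 and 16302265 counts, and the NECA libraries 15917018, 18065078 and 17895486. The libraries other than NECA replicate 2 resembled each other, with a median correlation with the other libraries of 0.949 to 0.979 across genes, which are not independent replicates. NECA replicate 2 had a median correlation of 0.870. Xist and the Y-linked transcripts separated 1 library of each group from the rest. DMSO replicate 2 and NECA replicate 1 had 14 and 11 Xist counts and 2495 and 2538 counts from the Y chromosome, whereas the other 4 libraries had at least 2956 Xist counts and at most 63 from the Y chromosome. By these transcripts each group held male and female tissue, and so tissue from more than 1 animal.

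The genes named by rank as lower in NECA included a creatine synthesis enzyme, adenosine deaminase and interferon-induced genes. Gatm (ENSMUSG00000027199, chromosome 2, 122594467 to 122611303, GRCm38), which encodes the amidinotransferase of creatine synthesis, was at 63.9 ± 29.6 CPM in DMSO and 13.3 ± 0.654 CPM in NECA (SD, n = 3 per group), a log2 fold change of -2.26 (SE 0.33). Ada (ENSMUSG00000017697, chromosome 2, 163726584 to 163750239), the deaminase that converts adenosine to inosine, was at 56.0 ± 11.5 and 17.6 ± 6.92 CPM, a log2 fold change of -1.67 (SE 0.31). Ifit2 (ENSMUSG00000045932, chromosome 19, 34550694 to 34576419), an interferon-induced gene, was at 574 ± 63.8 and 145 ± 85.6 CPM, a log2 fold change of -1.99 (SE 0.40). In the direction of lower levels in NECA, Ifi44 (-1.14, SE 0.20), another interferon-induced gene, and Areg (-1.08, SE 0.23), which encodes the growth factor amphiregulin, completed the list of 5 named by rank. In the opposite direction the ranked genes were Frmd8 (0.69, SE 0.13), Arnt2 (1.02, SE 0.22), Hes2 (0.93, SE 0.21), Vat1 (0.66, SE 0.16) and the clock-output transcription factor Dbp (1.08, SE 0.26). In each of these 10 genes the 3 libraries of one group lay above the 3 of the other, as the naming rule required.

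None of these genes passed the threshold after correction: the 10 had an adjusted p of 0.738 with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. Of 15847 genes, edgeR called 0, the smallest adjusted p was 0.589, and 868 genes had an unadjusted p under 0.05 (388 higher and 480 lower in NECA). The groups did not overlap in 2164 genes, or 13.7%, where chance gives 10%. DESeq2 called 9 genes. The 2 that rose by that test were Slc7a15, of an amino acid transporter family (2.45, SE 0.36, DESeq2 adjusted p = 1.2e-07), and Gml (2.52, SE 0.54). The 7 that fell were Gatm (-2.24, DESeq2 adjusted p = 5.05e-07), Ifit2 (-1.97), Ada (-1.65), Ubd (-2.56), Pdx1 (-3.41), Ifi44 (-1.12) and Cyp4v3 (-1.70). Slc7a15 had 21, 25 and 20 counts in DMSO and 112, 121 and 154 in NECA, and lay below the expression limit of the naming rule. Slc7a15, Gml, Ubd and Cyp4v3 were named after their values were seen. Without NECA replicate 2, edgeR called 0 of 16121 genes (885 at an unadjusted p under 0.05) and DESeq2 called 30, of which 7 were among the 9. Ifit2 and Pdx1 were the others of the 9 and were not called in that fit. Without the expression filter edgeR called 2 genes, Slc7a15 (adjusted p = 0.0227) and Gatm (adjusted p = 0.0189).

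**Figure D1:**
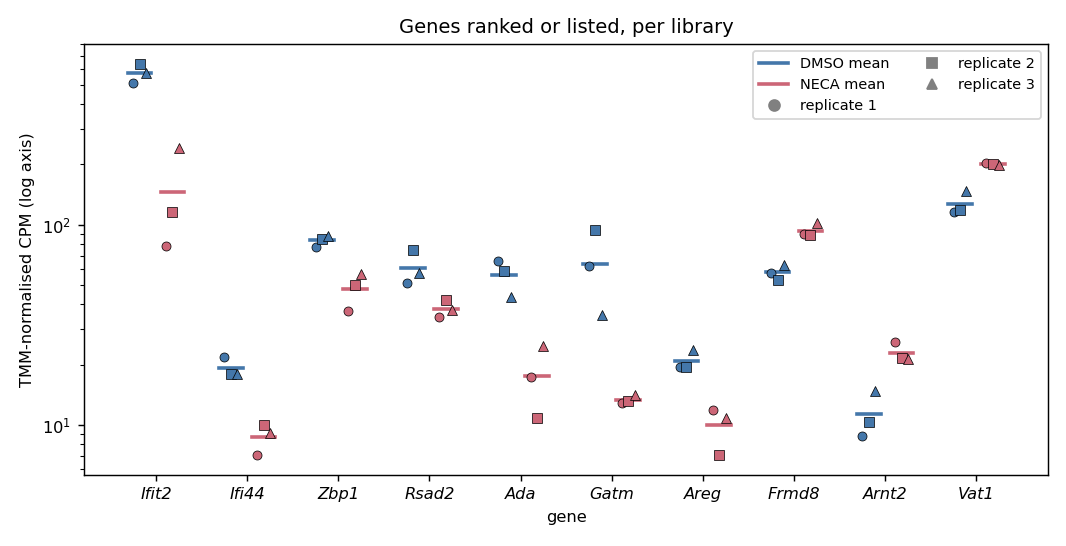
Levels of 10 genes in each library, as TMM-normalised CPM on a log axis; points are libraries (marker shape gives the replicate number) and bars are the means of the 3 DMSO and the 3 NECA libraries. In Ifit2 the means are 574 CPM in DMSO and 145 CPM in NECA. Zbp1 and Rsad2 are from the interferon list, and the points of their groups do not overlap. The other genes shown were named by rank under a rule that required groups without overlap. Hes2 and Dbp, also named by rank, are not shown.

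Of the 50 gene lists tested, 20 passed the camera threshold with the preset correlation of 0.01, 8 higher and 12 lower in NECA. With a correlation estimated from the data 0 of them passed, the smallest adjusted p being 0.716, and fry called 0 lists (smallest adjusted p 0.484). With edgeR adjusted over all genes, 0 members of any list passed. Other divisions of the same 6 libraries into 3 and 3 gave up to 25 lists with the preset correlation. Without NECA replicate 2, 21 lists passed with the preset correlation, 12 of them in the same direction as with all libraries and 1, cholesterol synthesis, in the opposite direction. With an estimated correlation 0 lists passed without any 1 of the 6 libraries, the smallest adjusted p being 0.413 without DMSO replicate 3 and 0.731 without NECA replicate 2.

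Interferon-stimulated genes were lower in NECA. Of the 34 genes on the list, 27 were lower and 7 higher, with a median log2 fold change of -0.30 (camera adjusted p = 1.26e-07; adjusted p = 0.716 with an estimated correlation). Adjusted over the list alone, 4 members passed, Ifi44, Ifit2, Zbp1 and Rsad2, against 0 over all genes. Zbp1, a sensor of nucleic acids, was at 83.4 ± 5.29 CPM in DMSO and 47.8 ± 10.0 CPM in NECA (log2 fold change -0.80, SE 0.18), and Rsad2, which encodes the antiviral enzyme viperin, at 61.1 ± 12.1 and 37.9 ± 3.79 CPM (-0.69, SE 0.18). The groups did not overlap in 8 of the 34 members, each lower in NECA, and overlapped in the rest. The mean of the list was 5.34, 5.41 and 5.56 log2 CPM in the DMSO libraries and 4.47, 5.49 and 5.03 in the NECA libraries. By that mean NECA replicate 2 lay above DMSO replicates 1 and 2. Igtp was at 94.9, 80.0 and 107 CPM in the DMSO libraries and at 23.3, 177 and 45.8 CPM in the NECA libraries, and Iigp1 at 72.9, 25.6 and 92.8 against 12.7, 146 and 45.8 CPM, so that both were highest in NECA replicate 2 and lowest in NECA replicate 1. Without NECA replicate 2, DESeq2 called Igtp (-1.43, SE 0.28, DESeq2 adjusted p = 0.000781) and the related Irgm2 (-1.12, SE 0.26, DESeq2 adjusted p = 0.0101) as lower. Ifi44 kept its DESeq2 call in that fit (-1.24, SE 0.25, DESeq2 adjusted p = 0.000945). Ifit2, at a DESeq2 adjusted p of 0.000978 with all libraries, was no longer called. The list median was -0.67 without NECA replicate 2 (camera adjusted p = 5.76e-22; adjusted p = 0.731 with an estimated correlation), -0.12 without NECA replicate 1 (camera adjusted p = 0.00996; 0.716 with an estimated correlation) and -0.18 without DMSO replicate 3 (camera adjusted p = 0.000766; 0.818 with an estimated correlation).

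Markers of B cells, of monocytes and macrophages and of T and innate lymphoid cells were lower in NECA. So was a list that joins dendritic cell and MHC class II genes. The neutrophil and mast cell lists did not pass. All 10 tested B cell and plasma cell markers were lower, with a median log2 fold change of -2.41 (camera adjusted p = 1.43e-09; adjusted p = 0.716 with an estimated correlation). Adjusted over the list alone, 4 passed, against 0 over all genes: the B cell receptor component Cd79b (-1.81, SE 0.43) and the immunoglobulin genes Ighm (-1.52, SE 0.36), Ighd (-2.93, SE 0.95) and Igkc (-3.48, SE 1.05; -5.38, SE 1.25 without NECA replicate 2, over the 1 and 2 counts then left in NECA). The DMSO libraries were not alike in these genes. Igkc had 91, 100 and 9 counts in DMSO and 1, 17 and 2 in NECA, and Cd79a had 122, 152 and 10 against 2, 34 and 4, so that DMSO replicate 3 lay below NECA replicate 2 in both. Cd79a, like Igtp, Irgm2 and Iigp1, was named after its values were seen. With the preset correlation the list kept its call without each library in turn (adjusted p = 0.413 to 0.847 with an estimated correlation), with a median of -1.70 without DMSO replicate 2, -1.80 without DMSO replicate 1, -2.55 and -2.64 without NECA replicates 3 and 1, and -3.46 without DMSO replicate 3. It was -3.45 without NECA replicate 2, over the 14 markers that then passed the filter, and the same with the 1 gene at 0 in the remaining NECA libraries held at a floor of 3 counts over the group.

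Among monocyte and macrophage markers, 20 of 22 were lower in NECA, with a median of -0.44 (camera adjusted p = 8.91e-05; adjusted p = 0.738 with an estimated correlation), and 0 passed either over all genes or adjusted over the list alone. The leading members were the chemokine receptor Cx3cr1 (-0.73, SE 0.22), Mrc1 (-0.60, SE 0.19), Cd68 (-0.66, SE 0.24) and Fcer1g (-0.47, SE 0.17). Dendritic cell and MHC class II genes had a median of -0.36, with 13 of 16 lower (camera adjusted p = 0.00454; adjusted p = 0.716 with an estimated correlation), and 0 members passed adjusted over the list alone. H2-Eb1 was at 105 ± 13.3 CPM in DMSO and 76.2 ± 9.98 CPM in NECA (-0.46, SE 0.16), H2-Aa differed by -0.49 (SE 0.18) and H2-Ab1 by -0.40 (SE 0.18), and H2-DMb2 by -1.45 (SE 0.57). These leading members are all MHC class II genes, so they do not show a difference in dendritic cells as such. H2-DMb2 had 77, 88 and 18 counts in DMSO and 18, 36 and 20 in NECA. As in Igkc and Cd79a, DMSO replicate 3 lay below NECA replicate 2. T cell, NK and innate lymphoid markers had a median of -0.47, with 14 of 17 lower (camera adjusted p = 0.0258; adjusted p = 0.716 with an estimated correlation) and 0 past the threshold adjusted over the list alone, among them Cd4 (-0.77, SE 0.27), Cd8a (-0.74, SE 0.43) and Trbc2 (-0.60, SE 0.39; -0.98, SE 0.41 without NECA replicate 2 and -0.37 without NECA replicate 1). Cd8a differed by -0.49 without DMSO replicate 2. The MHC class II call ended without DMSO replicate 1 (median -0.35, camera adjusted p = 0.0669) or NECA replicate 1 (-0.23, 0.177), with a median of -0.21 without DMSO replicate 3. The lymphoid call ended without DMSO replicate 1 (-0.27, 0.534), DMSO replicate 2 (-0.26, 0.245) or NECA replicate 1 (-0.35, 0.119).

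Genes that mark position along the bowel differed between the groups and also among the libraries of each group. All 14 jejunal and proximal genes were lower in NECA, with a median of -0.60 (camera adjusted p = 2.94e-07; adjusted p = 0.716 with an estimated correlation), and Ada and Pdx1 passed adjusted over the list alone, against 0 over all genes. Pdx1, a transcription factor of the duodenum and pancreas, was at 15.7, 10.9 and 2.31 CPM in the DMSO libraries and 1.87, 0.199 and 0.631 CPM in the NECA libraries (-3.46, SE 0.88). With the position score as a covariate, which itself includes Pdx1, the gene differed by -1.78 (SE 0.46). Bche (-0.64, SE 0.29) and Gkn3 (-1.02, SE 0.52) followed. The ileal list was higher in NECA, with 11 of 13 genes higher and a median of 0.53 (camera adjusted p = 0.00632; adjusted p = 0.716 with an estimated correlation), and 0 members passed adjusted over the list alone. Its leading genes were Muc3 (1.92, SE 0.68), Osr2 (1.497, SE 0.63), Fgf15 (3.21, SE 1.67), a hormone made in the ileum in response to bile acids, with 0, 0 and 231 counts in DMSO and 65, 1949 and 549 in NECA, and the bile acid transporter subunit Slc51a (0.53, SE 0.30). Muc3 differed by 1.20 (SE 0.58) without NECA replicate 2, Fgf15 by 1.90 (SE 1.58), Slc51a by 0.24 (SE 0.23), Bche by -0.39 (SE 0.22) and Gkn3 by -0.60 (SE 0.38). Without DMSO replicate 3, Osr2 differed by 2.61, Muc3 by 2.77 and Slc51a by 0.78. Fgf15 had 0 counts in the DMSO libraries then left, so its fitted 12.6 is not a measured fold. Fabp6, the ileal bile acid binding protein, was named after its values were seen and had 1, 3 and 2159 counts in DMSO and 0, 38381 and 2605 in NECA. The position score, in which a higher value is more proximal, was 3.08, 2.996 and 0.911 in the DMSO libraries and 2.20, -2.68 and 0.462 in the NECA libraries. Without NECA replicate 2 the jejunal median was -0.24 (camera adjusted p = 0.00586; 0.745 with an estimated correlation) and the ileal median 0.23 (camera adjusted p = 0.142). Without NECA replicate 1 the jejunal median was -0.98.

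**Figure D2:**
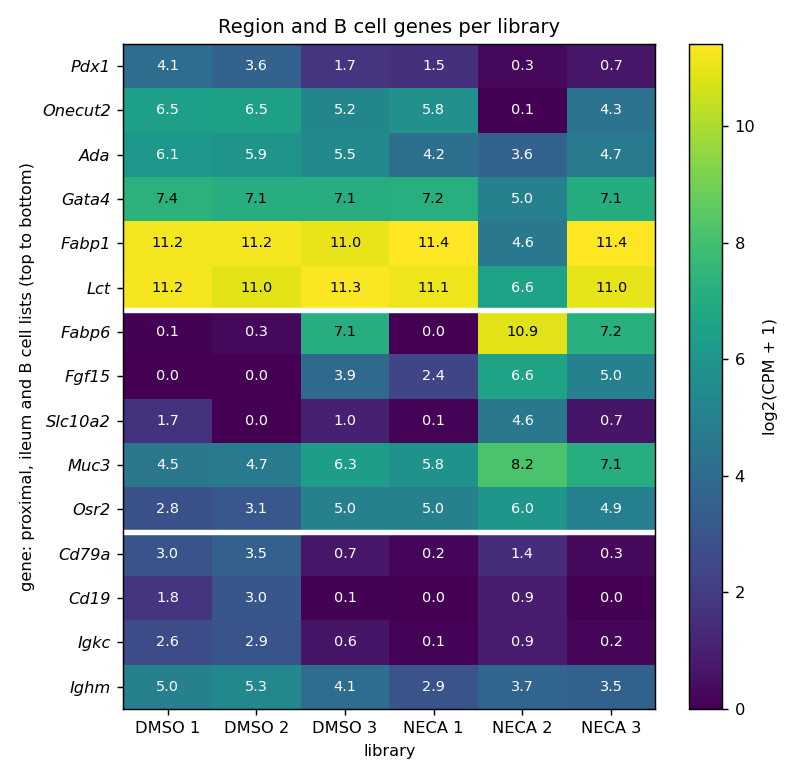
Levels of proximal, ileal and B cell genes (rows, from the fixed lists) in the 6 libraries (columns), with colour and printed value both giving log2(CPM + 1). Fabp6 reached 1913 CPM in NECA replicate 2 and 135 and 150 CPM in DMSO replicate 3 and NECA replicate 3, and Cd79a was highest in DMSO replicates 1 and 2, at 6.81 and 10.2 CPM.

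Paneth cell, antimicrobial, proliferation and cholesterol synthesis genes were higher in NECA, with their highest levels in NECA replicate 2. In that library all genes annotated to the mitochondrial chromosome took 1.31% of the counts, against 2.80% to 8.39% in the others. Of the 11 Paneth cell markers (Paneth cells are the defensin-secreting cells of the crypt base), 9 were higher, with a median of 0.97 (camera adjusted p = 0.000606; adjusted p = 0.716 with an estimated correlation). Of the 23 antimicrobial genes 19 were higher, with a median of 0.85 (camera adjusted p = 0.00139; adjusted p = 0.738 with an estimated correlation). In both lists 0 members passed adjusted over the list alone. The defensin Defa30 had 7, 0 and 24 counts in DMSO and 17, 125 and 92 in NECA, and the lectin Reg3g had 108, 38 and 1128 against 154, 23047 and 1044. Defa17 (3.26, SE 1.55), Defa22 (2.84, SE 1.39), Reg3a (1.20, SE 0.53) and the Wnt receptor Fzd5 (0.53, SE 0.21) were the other leading members. These folds were smaller without NECA replicate 2, at 0.27 (SE 1.18) for Defa17, 1.93 (SE 1.43) for Defa22, 0.77 (SE 0.55) for Reg3a and 0.27 (SE 0.13) for Fzd5. That of Reg3g went from 3.95 (SE 1.83) to 0.41 (SE 1.23). Of the Defa17 counts, 610 were in NECA replicate 2, against 11 and 36 in the other NECA libraries and 4, 1 and 51 in DMSO. Without DMSO replicate 3 the differences were 6.14 for Defa17, 4.30 for Defa30, 5.06 for Defa22 and 6.56 for Reg3g. Defa22 had 2, 0 and 13 counts in DMSO and 0, 86 and 41 in NECA. All 29 proliferation genes were higher, with a median of 0.46 (camera adjusted p = 3.13e-05; adjusted p = 0.760 with an estimated correlation), led by Mcm2 (0.56, SE 0.19) and with Bub1b (0.60, SE 0.28), Mcm3 (0.69, SE 0.35) and Mcm7 (0.78, SE 0.40) next. The latter 3 differed by 0.22 (SE 0.17), 0.13 (SE 0.15) and 0.15 (SE 0.21) without NECA replicate 2. All 25 cholesterol synthesis genes were higher as well, with a median of 0.60 (camera adjusted p = 0.000164; adjusted p = 0.760 with an estimated correlation), among them Hsd17b7 (0.45, SE 0.22), Stard4 (0.75, SE 0.41) and Lss (0.90, SE 0.51). They differed by 0.20 (SE 0.17), 0.13 (SE 0.24) and -0.03 (SE 0.20) without NECA replicate 2. Members passing adjusted over the list alone numbered 0 in both.

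Without NECA replicate 2 the median of proliferation genes was -0.10 (camera adjusted p = 0.527) and that of cholesterol synthesis -0.17 (camera adjusted p = 0.0481; 0.806 with an estimated correlation), both opposite in sign. The Paneth median was 0.46 without that library (camera adjusted p = 0.0173; 0.772 with an estimated correlation), 2.56 without DMSO replicate 3 and 1.51 without NECA replicate 1. The antimicrobial median was 0.30 without NECA replicate 2 (0.279) and 0.63 without DMSO replicate 2 (0.22), which ended the call in each case, and 1.44 and 1.49 without DMSO replicates 1 and 3. The cholesterol median was 0.92 without NECA replicate 1.

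The unfolded protein response and the tight junction list were higher in NECA by small amounts. In the former, 17 of 25 genes were higher, with a median of 0.35 (camera adjusted p = 0.00492; adjusted p = 0.716 with an estimated correlation), led by the endoplasmic reticulum chaperone Hyou1 (0.63, SE 0.24), Chac1 (1.17, SE 0.46), Edem1 (0.41, SE 0.17) and Manf (0.53, SE 0.23). Hyou1 differed by 0.35 (SE 0.16) without NECA replicate 2, Chac1 by 0.63 (SE 0.43), Edem1 by 0.37 (SE 0.18) and Manf by 0.27 (SE 0.16). In the latter, 23 of 26 were higher, with a median of 0.14 (camera adjusted p = 0.0123; adjusted p = 0.738 with an estimated correlation), among them the junction protein Cgn (0.56, SE 0.24), Marveld3 (0.36, SE 0.18) and Tjp3 (0.37, SE 0.20). Cgn and Tjp3 differed by 0.36 (SE 0.20) and 0.21 (SE 0.16) without NECA replicate 2, and Marveld3 by 0.22 without DMSO replicate 2. Cytosolic ribosomal protein genes had 32 of 39 members higher and a median of 0.12 (camera adjusted p = 0.0170; adjusted p = 0.760 with an estimated correlation), led by Rps28 (0.47, SE 0.18), Rpl37 (0.40, SE 0.16), Rps2 (0.57, SE 0.30; 0.23, SE 0.17 without NECA replicate 2) and Rps3 (0.45, SE 0.24; 0.29, SE 0.18 without it). In these 3 lists 0 members passed adjusted over the list alone. The unfolded protein call ended without DMSO replicate 1 (median 0.26, camera adjusted p = 0.0635), and its median was 0.14 without NECA replicate 2. The tight junction call ended without DMSO replicate 2 (0.09, 0.232), with a median of 0.22 without DMSO replicate 3, and the ribosomal call ended without NECA replicate 2 (0.03, 0.423) or DMSO replicate 3 (0.14, 0.102), with a median of 0.19 without NECA replicate 1.

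Mitochondrial transcripts and the genes of muscle and connective tissue were lower in NECA. All 13 mitochondrially encoded genes were lower, with a median of -1.09 (camera adjusted p = 3.39e-09; adjusted p = 0.716 with an estimated correlation), led by mt-Nd4 (-1.56, SE 0.63), mt-Nd2 (-1.40, SE 0.58), mt-Co3 (-1.33, SE 0.56) and mt-Nd6 (-0.98, SE 0.41). All genes annotated to the mitochondrial chromosome, listed or not, took 4.49%, 8.39% and 3.61% of the counts in DMSO and 3.63%, 1.31% and 2.80% in NECA. The list median was -0.56 without DMSO replicate 2, where mt-Nd2 differed by -0.90 and mt-Nd6 by -0.53. Of 32 nuclear-encoded respiratory chain genes 26 were lower, with a median of -0.20 (camera adjusted p = 0.00809; adjusted p = 0.760 with an estimated correlation), led by Cox7a2 (-0.60, SE 0.26), Atp5j (-0.40, SE 0.21), Cox6b1 (-0.42, SE 0.22) and Ndufs4 (-0.32, SE 0.18). The first 3 differed by -0.35 (SE 0.14), -0.22 (SE 0.14) and -0.24 (SE 0.15) without NECA replicate 2, and Ndufs4 by -0.18 without DMSO replicate 2. All 23 smooth muscle genes were lower, with a median of -0.50 (camera adjusted p = 0.000313; adjusted p = 0.760 with an estimated correlation), among them Pcp4 (-0.98, SE 0.51), Lmod1 (-0.57, SE 0.29), Synpo2 (-0.54, SE 0.28) and the contractile gene Cnn1, with 3466, 4513 and 1967 counts in DMSO and 2108, 2513 and 2685 in NECA. In these 3 lists 0 members passed adjusted over the list alone. The respiratory chain median was -0.07 without NECA replicate 2, which ended the call (camera adjusted p = 0.456), and -0.11 without DMSO replicate 2. The smooth muscle call ended without DMSO replicate 2 (median -0.04, camera adjusted p = 0.990). In that fit Pcp4 differed by -0.19, Lmod1 by -0.15, Synpo2 by -0.16 and Cnn1 by -0.19.

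Of 32 fibroblast and extracellular matrix genes 22 were lower, with a median of -0.11 (camera adjusted p = 0.0439; adjusted p = 0.760 with an estimated correlation). Elastin (Eln) was at 500 ± 23.4 CPM in DMSO and 347 ± 41.6 CPM in NECA (-0.52, SE 0.18), and its crosslinking enzyme Lox at 30.6 ± 4.69 and 20.4 ± 2.10 CPM (-0.59, SE 0.17). Foxf1 (-0.29, SE 0.12) and Mfap5 (-0.77, SE 0.33; -0.50 without DMSO replicate 1) were also lower. Tuft cell markers (chemosensory epithelial cells) had 8 of 9 members lower and a median of -0.61 (camera adjusted p = 0.00289; adjusted p = 0.716 with an estimated correlation), with Ptgs1 at 41.3 ± 0.215 and 32.5 ± 3.21 CPM (-0.35, SE 0.14), Alox5ap (-0.87, SE 0.38), Dclk1 (-0.61, SE 0.30) and Bmx (-0.69, SE 0.34). In both lists 0 members passed adjusted over the list alone. Of the 8 adipocyte genes 7 were lower, with a median of -0.43 (camera adjusted p = 0.00483; adjusted p = 0.716 with an estimated correlation). Adjusted over the list alone Lpl (-0.86, SE 0.26) and Car3 (-2.16, SE 0.55) passed, against 0 over all genes, and Plin4 (-0.58, SE 0.39) and Cidea (-0.41, SE 0.40) followed. Without DMSO replicate 2, Car3 differed by -1.37, Plin4 by -0.04, Cidea by -0.11 and the tuft cell gene Dclk1 by -0.32. The fibroblast call ended without DMSO replicate 1 (median -0.08, camera adjusted p = 0.534), DMSO replicate 3 (-0.12, 0.28), NECA replicate 1 (-0.13, 0.126) or NECA replicate 2 (-0.10, 0.0522), with a median of -0.18 without DMSO replicate 2. The adipocyte median was -0.20 without NECA replicate 2, which ended the call (camera adjusted p = 0.293), -0.24 without DMSO replicate 2 and -0.72 without NECA replicate 1, and the tuft median was -0.35 without DMSO replicate 2.

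**Figure D3:**
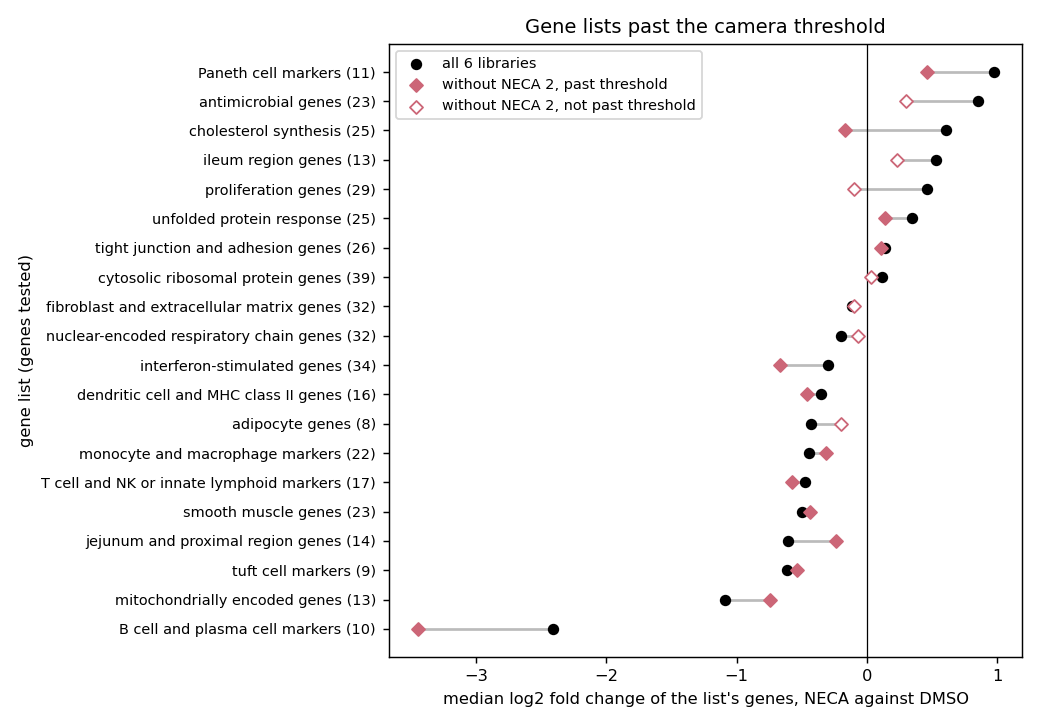
Median log2 fold change, NECA against DMSO, of the 20 gene lists past the camera threshold with the preset correlation (number of genes tested in brackets); circles are fits with all 6 libraries, and diamonds fits without NECA replicate 2, filled where the list was past the threshold in that fit (cholesterol synthesis in the opposite direction). The medians of proliferation genes moved from 0.46 to -0.10 and those of interferon-stimulated genes from -0.30 to -0.67.

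The genes of adenosine signalling did not pass the list test. The list of adenosine receptors and adenosine metabolism had a median of -0.07 over 21 genes (camera adjusted p = 0.137), and Ada was its 1 member past the threshold adjusted over the list alone (adjusted p = 0.0151, edgeR), against 0 over all genes. Ada also belongs to the proximal list, and its log2 fold change was -1.24 (SE 0.29) with the position score as a covariate. The score itself includes Ada, and edgeR called 0 genes in that fit, so the value does not separate Ada from position. The receptor genes Adora1 (0.29, SE 0.39), Adora2a (-0.07, SE 0.23) and Adora3 (-0.86, SE 0.67) differed by less than 2 SE. Adora1 differed by 0.599 (SE 0.30) without NECA replicate 2 and Adora3 by -0.38 (SE 0.61). With each library left out in turn Adora1 ran from -0.14 to 0.599, Adora2a from -0.16 to 0.01 and Adora3 from -1.49 to -0.38. Adora2b was at 63.1 ± 11.7 CPM in DMSO and 36.4 ± 32.3 CPM in NECA (-0.79, SE 0.76), with 79 counts in NECA replicate 2 against 569 to 1195 in the other 5 libraries, and differed by -0.26 (SE 0.27) without it and by -1.64 without NECA replicate 3. The cAMP and CREB response list, downstream of the adenosine receptors that couple to cAMP, had a median of -0.02 over 21 genes (camera adjusted p = 0.456), with Areg past the threshold adjusted over the list alone (adjusted p = 0.0366, edgeR) and 0 over all genes. With the preset correlation the adenosine list passed, lower, without DMSO replicate 2 (median -0.09, camera adjusted p = 0.0313; 0.497 with an estimated correlation) or NECA replicate 3 (-0.11, 0.0287; 0.664 with an estimated correlation). Its median was -0.14 without NECA replicate 1. That of the cAMP list ran from -0.11 to 0.02 with each library left out in turn.

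Several of the myeloid and inflammatory genes fixed beforehand had few counts. S100a8 had 18, 8 and 5 counts in DMSO and 11, 15 and 25 in NECA (0.62, SE 0.53), and S100a9 had 37, 5 and 7 against 20, 21 and 19 (0.24, SE 0.66). Without DMSO replicate 1 they differed by 1.17 and 1.53, and without NECA replicate 3 S100a8 differed by 0.23. S100a9 turned in sign, to -0.15, without DMSO replicate 2. Ly6g, Il6 and Il10 had at most 2 counts in any library and were not tested, so that no difference in them was detectable at this depth. Arg1 (0.20, SE 0.35), Il1b (-0.47, SE 0.44), Tnf (-0.45, SE 0.52) and Ptgs2 (-0.52, SE 0.31) differed by less than 2 SE. With each library left out in turn Arg1 ran from -0.05 to 0.43, Il1b from -0.78 to -0.16, Tnf from -0.78 to 0.22 and Ptgs2 from -0.698 to -0.33. Nos2 had 246 counts in NECA replicate 2 and 9 to 37 in the other libraries, with a log2 fold change of 1.60 (SE 1.03) that was -0.67 (SE 0.63) without that library. The list of neutrophil and granulocytic MDSC markers had a median of -0.07 over 14 genes (camera adjusted p = 0.192), with 7 genes higher and 7 lower, the list of MDSC suppressive function -0.01 over 20 genes (0.356), and the list of inflammatory cytokines and chemokines -0.09 over 25 genes (0.168). In each, 0 members passed adjusted over the list alone. In the neutrophil list 5 genes had an unadjusted p under 0.05, each lower in NECA and named after its values were seen: Itgam (-0.91, SE 0.25), Ncf1 (-0.69, SE 0.20), Csf3r (-1.14, SE 0.38), Cd84 (-0.70, SE 0.27) and Ngp (-1.76, SE 0.71). With the preset correlation the inflammatory list passed, lower in NECA, without NECA replicate 2 (median -0.38, camera adjusted p = 0.0173; adjusted p = 0.731 with an estimated correlation) or DMSO replicate 2 (-0.32, 0.00854), and the neutrophil list without DMSO replicate 2 (-0.35, 0.000528). With an estimated correlation both had an adjusted p of 0.449 without DMSO replicate 2. With each library left out in turn the neutrophil median ran from -0.37 without NECA replicate 1 to 0.06 without NECA replicate 2, the inflammatory median from -0.38 to -0.08 and that of MDSC suppressive function from -0.07 to 0.07.

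Barrier, stem cell and enterocyte genes fixed beforehand did not pass the threshold. The tight junction genes Ocln (134 ± 25.0 and 136 ± 2.06 CPM; 0.02, SE 0.17) and Tjp1 (0.27, SE 0.16), the stem cell gene Lgr5 (-0.10, SE 0.28) and the division marker Mki67 (0.26, SE 0.33) differed by less than 2 SE. Lgr5 differed by -0.46 (SE 0.21), more than 2 SE, without NECA replicate 2, and Mki67 by -0.23 (SE 0.15), opposite in sign. Lgr5 also turned without NECA replicate 1 (0.12) and Ocln without DMSO replicate 2 (-0.11), where Tjp1 differed by 0.16. The mucin Muc2 was at 121 ± 68.0 CPM in DMSO and 225 ± 271 CPM in NECA (0.90, SE 0.85), and at -0.81 (SE 0.48) without NECA replicate 2. Lactase (Lct) was at 2339 ± 318 and 1460 ± 1183 CPM (-0.68, SE 0.87), with 1969 counts in NECA replicate 2 and at least 29679 in the others. It differed by -0.12 (SE 0.18) without that library and -1.13 without NECA replicate 1. Among goblet cell markers 16 of 19 were higher (median 0.46, camera adjusted p = 0.182), and the list passed as higher without DMSO replicate 1 (0.65, camera adjusted p = 0.00377), NECA replicate 1 (0.83, 0.00276) or NECA replicate 3 (0.72, 0.0145). With an estimated correlation its adjusted p in these fits was 0.847, 0.716 and 0.733. Its median was 0.09 without DMSO replicate 2, and without NECA replicate 2 it passed as lower (-0.51, camera adjusted p = 0.0168; adjusted p = 0.772 with an estimated correlation).

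The remaining lists did not pass with all 6 libraries, and in each 0 members passed over all genes or adjusted over the list alone. The epithelial lists were mature enterocytes (median -0.25, camera adjusted p = 0.192), suckling-type enterocytes (-0.01, 0.931), adult-type enterocyte genes (-0.19, 0.606), stem cells (-0.01, 0.931), enteroendocrine cells (0.01, 0.931), lipid absorption (-0.18, 0.125), PPARA targets and ketogenesis (-0.11, 0.125), bile acid transport and FXR targets (0.32, 0.632) and the colon region (-0.48, 0.0618). The lists of other cells were endothelium (-0.17, 0.182), enteric neurons and glia (-0.21, 0.190), interstitial cells of Cajal (-0.30, 0.166), mesothelium (-0.54, 0.383), skeletal muscle (0.11, 0.376), mast cells (-0.18, 0.611), erythroid cells (0.04, 0.456), pancreatic acinar cells (-0.36, 0.125) and hepatocytes (0.03, 0.931). The lists of cell states were hypoxia and glycolysis (0.18, 0.0585), heat shock (-0.09, 0.248), nuclear-retained RNAs (-0.53, 0.184), clock genes (0.09, 0.284), glucocorticoid response (0.17, 0.475) and apoptosis and p53 targets (0.01, 0.638). The median and the tested direction differed in sign for stem cell, erythroid and apoptosis genes. With an estimated correlation none of the calls that follow held, as 0 lists passed without any 1 library. Without NECA replicate 2, suckling-type genes (0.19), lipid absorption (0.11), PPARA targets (0.18), hepatocyte genes (0.22) and clock genes (0.09) passed as higher and the colon region (-0.76) as lower. Without DMSO replicate 2, lipid absorption (-0.23), PPARA targets (-0.18), endothelium (-0.25), the colon region (-0.46), acinar cells (-0.74) and mast cells (-0.54) passed as lower, and clock genes (0.18), enteric neurons and glia (0.13) and mesothelium (0.35) as higher. Lipid absorption, PPARA targets, mature enterocytes and endothelium passed as lower without NECA replicate 1 (-0.41, -0.48, -0.40 and -0.33) and without NECA replicate 3 (-0.34, -0.16, -0.42 and -0.26). Without NECA replicate 3, acinar (-0.39) and erythroid genes (-0.37) also passed as lower and hypoxia genes (0.21) as higher. Hypoxia genes (0.21) passed as higher without DMSO replicate 1, and nuclear-retained RNAs (-0.75) and enteric neurons and glia (-0.36) as lower. Without DMSO replicate 3, enteric neurons and glia (-0.44), mesothelium (-0.85) and interstitial cells of Cajal (-0.55) passed as lower.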

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

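The fit without both replicates 2, the sex, position and robust-dispersion fits, DESeq2 without NECA replicate 2 and the estimated correlation with 1 library left out were chosen after the results were seen. edgeR called 0 genes under each alternative run with it except the absence of an expression filter, which gave 2. DESeq2 gave 9, and 30 without NECA replicate 2; the cause was not tested. At an unadjusted p under 0.05, leaving out 1 library in turn gave 506 to 1212 genes. Of the list counts, 0 passed with an estimated correlation (also 0 with each library left out in turn) and 0 with fry. Both tests allow for the correlation between genes in these libraries. Under the other alternatives 15 to 29 passed, where 20 did in the main analysis. Correlation is not the whole reason for the lost calls. The tuft list had an estimated correlation of -0.0188, below the preset 0.01, yet its unadjusted camera p went from 0.000636 to 0.0238. The simulated lists were tested with the preset correlation only, so the power of fry and of camera with an estimated correlation was not examined. No pairing by replicate number was seen: deviations of same-numbered libraries from their group means correlated at 0.0943, -0.189 and -0.116, and 1 of the 6 libraries correlated best with its own number. The check is weak, as NECA replicate 2 moves the mean from which the other NECA deviations were taken. A pairing is therefore not excluded. With the replicate number as a block, 0 genes (628 unadjusted) and 23 lists passed. Alternatives planned for normalized values (another pseudocount, quantile or median-of-ratios scaling of such values, limma without a trend) were not run, as the files hold counts. Depth limited genes such as Ly6g, Il6 and Il10, with 0 to 2 counts per library.

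The lists past the threshold in the main analysis or under the alternative whose tested direction turned follow, with their medians, which for some lists kept their sign; the cause was not tested unless a library is named. With 1 library left out at a time, medians ranged from -0.75 to -0.0411 for smooth muscle, -0.44 to 0.13 for enteric neurons and glia, -0.85 to 0.35 for mesothelium, -0.51 to 0.83 for goblet cells, -0.10 to 0.62 for proliferation, -0.24 to 0.19 for suckling-type enterocytes, -0.41 to 0.11 for lipid absorption, -0.48 to 0.18 for PPARA targets and -0.17 to 0.92 for cholesterol synthesis. The tested direction of the first 3 turned without DMSO replicate 2, that of smooth muscle with a median still below 0, and that of the others without NECA replicate 2. With library quality weights, goblet cell markers were at -0.52 and cholesterol synthesis at -0.0307. Without both replicates 2, the medians were -0.16 for antimicrobial genes, 0.22 for Paneth cells (tested direction lower), -0.81 for goblet cells, -0.17 for enteroendocrine cells, -0.078 for proliferation, 0.14 for lipid absorption, -0.20 for cholesterol synthesis, -0.00708 for smooth muscle (tested direction higher), 0.087 for enteric neurons and glia, 0.30 for mesothelium, 0.35 for erythroid genes and 0.011 for the nuclear-encoded respiratory chain. With the position score as a covariate, they were -0.0258 for antimicrobial genes, -0.73 for goblet cells, -0.28 for proliferation, 0.17 for mature enterocytes, 0.18 for lipid absorption, 0.25 for PPARA targets, -0.37 for cholesterol synthesis, 0.25 for erythroid genes and 0.0234 for the nuclear-encoded respiratory chain.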

Other observations

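The tests of the position of the piece and of the number of detected genes were chosen after the results were seen, while those of epithelium, white blood cells and the splits of the libraries were set before. NECA replicate 2 differed from the other 5 libraries in digestive and defence genes of the epithelium. The ileal bile acid binding protein Fabp6 was at 1913 CPM there and at most 150 CPM elsewhere, and the lectins Reg3b and Reg3g were at 5118 and 1149 CPM against at most 320 and 70.5 CPM. Guca2a, which encodes guanylin, the stearoyl-CoA desaturase Scd2 and the mucin Muc2 were at 970, 1115 and 538 CPM against at most 211, 188 and 181 CPM. In the other direction, Fabp1, the fatty acid binding protein of proximal enterocytes, was at 23.1 CPM against at least 2096 CPM, the membrane protease Mme at 1.40 against at least 192 CPM, the lipid transporter Mfsd2a at 1.54 against at least 236 CPM, and the milk-clotting enzyme Cym at 0.0997 against at least 48.5 CPM. By list, its median log2 deviation from the mean of the other 5 was 1.87 for goblet cells, 1.56 for Paneth cells, 1.52 for antimicrobial genes, 1.46 for cholesterol synthesis and 1.07 for proliferation, and -2.13 for the jejunal list, -1.91 for mitochondrially encoded genes, -1.49 for pancreatic acinar genes, -1.11 for mature enterocytes, -1.10 for lipid absorption, -1.05 for erythroid genes and -1.01 for PPARA targets. All genes annotated to the mitochondrial chromosome took 1.31% of its counts, against 2.80% to 8.39% in the others. These genes were chosen for the size of their deviation.

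For NECA replicate 2, loss of the epithelium as a whole would lower the median deviation of pan-epithelial genes. Over 16 such genes it was 0.43 (SE 0.09 over genes of this 1 library), which argues against such a loss. These genes cannot show a loss of part of the epithelium, which stays open. Mature enterocyte markers deviated by -1.11 and Paneth cell markers by 1.56. A shallow or low-complexity library is argued against by its 21946 detected genes, where the others had 21564 to 21841. A candidate explanation is a more distal piece of bowel: the ileal list deviated by 0.92 and the jejunal list by -2.13, a difference of 3.05. That difference was seen before the test was written, and the labels do not give the segment. A difference in RNA quality or cell content, to which its lower mitochondrial share could belong, and a response of the epithelium in that sample to NECA were not tested and stay open, the latter since the position of the piece and the treatment cannot be varied separately in 1 library.

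The lower interferon-stimulated genes in NECA might follow the position of the piece, as NECA libraries had a lower mean position score (by -2.33). Within groups, however, the list was higher toward the distal end, so that position predicted a shift of 0.42 (SE 0.08) where the observed mean difference was -0.44 (SE 0.30); without NECA replicate 2 the prediction was 0.17 (SE 0.08) and the difference -0.69. With the position score as a covariate the list median was -0.77. Its camera adjusted p was 1.64e-39 with the preset correlation and 0.208 with an estimated correlation, so that fit does not decide the question. The sign of the slope within groups, the same without NECA replicate 2, argues against position as the whole cause, though it rests on few libraries. A lower share of white blood cells stays open as a candidate: 14 of 16 pan-leukocyte genes were lower in NECA, with a median of -0.45. The mean of the list differed by -0.47 (SE 0.17). That is below the bound of -0.3 set beforehand for this explanation, though by slightly less than the SE. A lower leukocyte list does not by itself show that it caused the interferon difference. A response to NECA stays open too, as a hypothesis that these libraries do not separate from a change in cell makeup.

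The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes past the threshold with edgeR (868 at an unadjusted p under 0.05, 9 genes with DESeq2), and the highest of the other splits gave 0; a count of 0 is met by any split, so the comparison says nothing. At an unadjusted p under 0.05 the other splits gave 240 to 1195 genes. For gene lists with the preset correlation the real split gave 20 and the highest of the others 25, and 7 of the 10 splits gave at least 20.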
